A study of Mus musculus with 23 samples.

How the data were processed

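Per the labels, RNA from A404 cells was labelled with Cy5 and RNA from a pool of whole mouse embryos with Cy3, and both were hybridized to Agilent oligonucleotide arrays without a dye swap. Slides were read on an Agilent G2565AA scanner and quantified with Agilent Feature Extraction A.6.1.1. The labels give 6 Control, 5 RA48, 6 RA96 and 6 Puromycin arrays, 5 to 6 plates per replicate, and do not say whether replicates are separate cultures, so p-values measure the spread between these arrays, which may be technical. The deposited table holds a log10 ratio per probe and array as read here. The base of the logarithm, any centring and the direction of the ratio are not stated. The base was read as 10 from the range of the values, and values were divided by log10 of 2 (0.301) to give log2 ratios. The direction was read from the dyes, and Alb, the albumin gene, which fetal liver expresses, was negative in all 4 groups (means of -4.27, -4.37, -4.28 and -4.12). Intensities and background were not used here, so no limit of detection can be given.

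Of 21446 rows 1166 (5.44%) had at most 6 significant digits on every array, no gene, and 2243 exact zeros among them, and were left out as probable control spots. The other 20280 probes comprised 11100 with 1 gene symbol, 442 with several and 8738 with none, and the reference table of probes gave the symbols. For 37 probes the gene identifier found no match, and no symbol was updated. Probes with 1 symbol were averaged per gene within each array (1926 genes had more than 1 probe), which with the remaining probes as single rows gave 17863 rows, 8683 of them genes. No value was missing, so the requirement of 3 values per group removed nothing. No normalization between arrays was added.

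Group means of all 23 arrays were fitted in 1 model with limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and Benjamini-Hochberg adjustment per comparison over all rows. Rows with an adjusted p under 0.05 are called. The 5 comparisons, the F test over 4 groups, the gene lists, the rule for named genes and the first group of other settings below were fixed before the data were examined. For 38 gene lists written from general knowledge (744 of 1120 listed genes on the array), camera with a preset correlation of 0.01 was run on the moderated statistics, adjusted over 190 tests, and repeated with a correlation estimated from the arrays and with fry, which tests whether the members move 1 way, not whether they differ from other genes. All 38 lists were tested in all 5 comparisons. Camera called 20 in RA48 versus Control, 12 in RA96 versus RA48 and 9 in Puromycin versus RA96. It called 20 in RA96 versus Control and 18 in Puromycin versus Control. The text describes part of them, so in each comparison some called lists are not described. Beside the count of called members stands the count adjusted over the list alone.

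Genes are named by a rule: Acta2, Cnn1, Myh11, Nanog and Rarb in every comparison, the 8 largest rises and the 8 largest falls per comparison (4 in RA96 versus Control) among called genes whose groups do not overlap, and up to 2 members each way per list described. The rule also held Tagln, Pou5f1 and Cyp26a1 in every comparison, but no probe carried their symbol alone, so they were not assessed. Symbols that are clone or predicted names were passed over. For the largest rises and falls, the lack of overlap and an adjusted p under 0.05 follow from this rule and are no further evidence. A gene outside this rule is marked as named after its values were seen.

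The other settings tried were median-centred arrays, quantile and scale normalization, single probes, only the groups compared, the replicate number as a block, array weights, trended and robust variance, other thresholds, rules on missing values, and leaving out each array in turn. Chosen after seeing the data were the array set as a block, each set alone, group and set as a random block (duplicateCorrelation, statmod 1.5.0), control-like rows kept, and ratios read as log2. The sets were taken from the first principal component of the deviations from group means. Other splits of the arrays were drawn 100 times with a fixed seed. Splits and permutations were run in R. Prep and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

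The fit was tested on simulated data of the same size with 200 changed rows. A log2 change of 1 was recovered in 77.6% of rows in RA48 versus Control, 70.1% in RA96 versus RA48, 80.6% in Puromycin versus RA96, 89.6% in RA96 versus Control and 76.1% in Puromycin versus Control. A change of 0.5 was recovered in 37.3%, 31.3%, 34.3%, 38.8% and 32.8%. These simulations hold the spread between arrays only. With the array sets simulated as well, a change of 0.5 was recovered in 31.3%, 38.8%, 38.8%, 35.8% and 40.3%, and with the set as a block in 59.7%, 49.3%, 56.7%, 56.7% and 59.7%. In these simulations changes of this size were thus often missed at these numbers of arrays. Recovery may differ in the real fits, where many more than 200 rows were called and the adjustment was less strict. The block fits were given the simulated sets, and 0 to 13 unchanged rows were called per fit.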

Results

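Gene expression was measured in A404 cells, a clone of the mouse P19 embryonal carcinoma line, at 4 points of a protocol that differentiates them towards smooth muscle. As background on the line, A404 cells carry a puromycin resistance gene under the promoter of Acta2, the smooth muscle alpha-actin gene. Undifferentiated cells formed the Control group (n = 6 arrays). Cells given 1 µmol/L all-trans retinoic acid formed the RA48 group after 48 h (n = 5) and the RA96 group after 96 h (n = 6). The Puromycin group (n = 6) had 96 h of retinoic acid and then 48 h of puromycin, and the labels do not say whether retinoic acid was kept on. Each of the 23 arrays compared red-labelled RNA of 5 to 6 plates with green-labelled RNA pooled from whole embryos of day 17.5. Values are log2 ratios of cell over embryo RNA. They were converted from deposited log ratios read as log10, a base that is not stated, so folds rest on that reading and p-values do not. All arrays held a value for every probe, and 17863 rows were compared, 8683 of them genes and the others single probes without a gene of their own.

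Within every group the arrays fell into 2 sets that the labels do not name. The first set held 11 arrays (Control replicates 1 to 3, RA48 replicates 1 to 3, RA96 replicates 1 and 3, and Puromycin replicates 1 to 3) and the second the other 12. This split carried 48.9% of the variance within groups, and the next component 10.6%. Pearson correlations across rows between arrays of 1 group were 0.83 to 0.98 within a set and 0.70 to 0.85 between sets. RA48 and RA96 were spread unevenly over the sets, with 3 and 2 arrays in the first and 2 and 4 in the second. Changes that involve these groups and are fitted without the set thus carry part of the shift between the sets, above all in RA96 versus RA48. Since each set holds arrays of all 4 groups, each comparison was also made with the set as a block and within each set. The p-values of those fits are optimistic, because the sets were defined from the same residuals.

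Between the 4 groups, 9406 of 17863 rows (52.7%) differed at an adjusted p under 0.05, among them 5279 of 8683 genes. Acta2 had mean log2 ratios of -4.90 ± 0.65 (SD, n = 6) in Control, -0.34 ± 0.14 (n = 5) in RA48, 1.87 ± 0.13 (n = 6) in RA96 and 2.40 ± 0.26 (n = 6) in Puromycin (limma F test, adjusted p = 2.82e-17). Sox2, a transcription factor of pluripotent and neural cells, went the other way, from 5.09 ± 1.56 in Control through 2.87 ± 0.32 and 0.63 ± 0.52 to -0.60 ± 0.55. Its Control mean holds 1 array at 8.18, with the others from 4.12 to 5.22. With the array set as a block 12718 rows differed, and 12474 and 10121 did within the first and second set. With group and set together as a random block, which treats arrays of 1 group and set as repeats, the count was 2851. That fit holds no term for the set, so the shift between the sets counts there as spread.

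**Figure D1:**
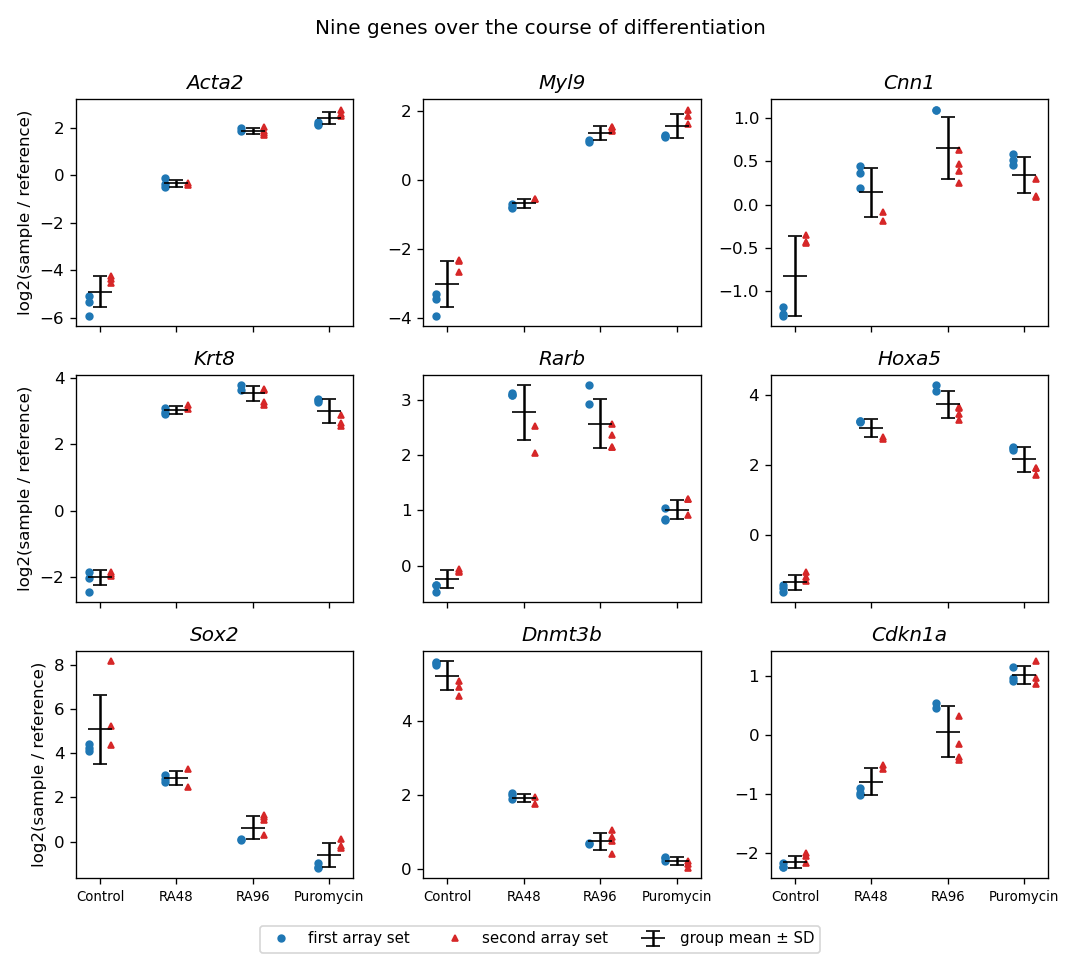
Log2 ratio of cell over embryo RNA (y axis) in each array of the 4 groups (x axis) for 9 genes, with the array set shown by the marker and the group mean ± SD beside the points. Acta2 climbs from a mean of -4.90 in Control to 2.40 in Puromycin, and Sox2 drops from 5.09 to -0.60.

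RA48 versus Control asked what changed in the first 48 h of retinoic acid (n = 5 and 6 arrays; changes are log2 differences ± SE). Acta2 rose by 4.56 ± 0.22, a 23.7-fold change. Rarb, a retinoic acid receptor, rose by 3.01 ± 0.20, the homeobox gene Hoxa5 by 4.42 ± 0.18 and Meis1, a homeodomain cofactor of Hox proteins, by 3.22 ± 0.15. The largest rise was that of Pmp22, a myelin membrane protein gene (5.55 ± 0.19), followed by Krt8, a keratin of simple epithelia (5.05 ± 0.15). Lgals3 (4.06 ± 0.22) and Lgals1 (3.96 ± 0.39), which encode galectins, Anxa1, an annexin gene (3.90 ± 0.18), and Tshz1, a zinc-finger factor gene (3.78 ± 0.12), rose too. The falls included those of Utf1, a chromatin factor of embryonic stem cells (-3.49 ± 0.13), Dnmt3b, a de novo DNA methyltransferase (-3.31 ± 0.14), and Otx2, a homeodomain factor (-2.77 ± 0.08). The largest fall was that of Pim2, a serine/threonine kinase gene (-4.32 ± 0.14). Gpr37, an orphan receptor gene (-3.26 ± 0.13), the imprinted genes Magel2 (-2.98 ± 0.13) and Snhg14 (-2.61 ± 0.18), and Sgk1, a kinase gene induced by serum and glucocorticoids (-2.49 ± 0.23), fell as well. Nanog, a core pluripotency factor, fell by 0.71 ± 0.17. Cnn1, the smooth muscle calponin gene, rose by 0.97 ± 0.20, by 1.58 within the first array set, and differed by 0.27 within the second (adjusted p = 0.0826). Myh11, the smooth muscle myosin heavy chain, differed by 0.07 ± 0.60 (adjusted p = 0.953), by 0.31 within the first set (0.0446) and by 0.21 within the second (0.504). For each of these genes but Myh11 the RA48 and Control arrays did not overlap, and the highest adjusted p among them was 0.00296 (Nanog). Each of them had 1 direction in both array sets, Acta2 with 5.11 and 4.01.

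Of 20 measured pluripotency genes 3 rose and 11 fell (3 and 13 adjusted over the list alone), and the median change was -0.54 (-0.54 in the first and -0.63 in the second array set). Pluripotency genes had camera adjusted p = 1.44e-09, 9.21e-10 with the array sets as a block, and adjusted p = 0.0963 with an estimated correlation. The risers were Lefty1, an inhibitor of Nodal signalling (2.03 ± 0.19), Klf4, a factor on both the pluripotency and the smooth muscle regulator lists (0.79 ± 0.21, and 0.59 with adjusted p = 0.122 within the second set), and Klf2, a related factor that was named after its values were seen (0.62 ± 0.20). In the retinoic acid response list, with 15 measured genes such as Rarb and Meis1, 9 rose and 0 fell (9 and 1 adjusted over the list alone), and the median was 0.74, with 0.74 and 0.52 within the first and second array set. Retinoic acid response genes had camera adjusted p = 9.22e-07, 4.91e-06 with the array sets as a block, and adjusted p = 0.0647 with an estimated correlation. Among 14 measured Hox genes 4 rose and 0 fell (4 and 1 adjusted over the list alone): Hoxa5, Hoxb9 (1.88 ± 0.21), and, named after their values were seen, Hoxb8 (1.48 ± 0.30) and Hoxb5 (1.16 ± 0.11). For the Hox list the median change was 0.14 (0.09 in the first and 0.31 in the second array set). Hox genes had camera adjusted p = 0.0221, 0.0626 with the array sets as a block, and adjusted p = 0.205 with an estimated correlation, so the block ended that call. Of 18 contractile genes of smooth muscle 13 rose and 0 fell (13 and 0 adjusted over the list alone), led by Acta2 and Csrp1, a LIM-domain protein gene (2.42 ± 0.30). For this list changes had a median of 1.06 (1.35 within the first and 0.98 within the second array set). Smooth muscle contractile genes had camera adjusted p = 2.15e-06, 5.77e-10 with the array sets as a block, and adjusted p = 0.248 with an estimated correlation. Genes of the actin cytoskeleton gave a like count, as 11 rose and 0 fell (12 and 1 adjusted over the list alone) of 20, with Tmsb4x, which binds actin monomers (2.47 ± 0.39), and Cnn2, a calponin gene (2.29 ± 0.10), in front. Here the median was 0.85, with 0.99 and 0.69 within the first and second array set. Actin cytoskeleton genes had camera adjusted p = 2.2e-07, 8.67e-11 with the array sets as a block, and adjusted p = 0.302 with an estimated correlation.

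Basement membrane genes rose as a group: 12 rose and 0 fell (15 and 0 adjusted over the list alone) of 17, among them Col18a1, a collagen gene (2.61 ± 0.09), and Nid1, which encodes nidogen (2.57 ± 0.18). For them the median change was 0.92 (1.35 in the first and 0.73 in the second array set). Basement membrane genes had camera adjusted p = 2.52e-09, 1.36e-08 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. The extraembryonic endoderm list shares laminin and collagen genes with that list, and 12 rose and 0 fell (12 and 0 adjusted over the list alone) of its 19 members, with Gata6, an endoderm and smooth muscle factor (2.04 ± 0.18; 2 of its 3 probes were called), and Lama1, a laminin chain gene (1.67 ± 0.19), rising most. For the endoderm list changes had a median of 0.67 (0.88 within the first and 0.40 within the second array set). Extraembryonic endoderm genes had camera adjusted p = 0.000241, 0.000828 with the array sets as a block, and adjusted p = 0.0638 with an estimated correlation. Epithelial genes (18 measured) gave a mixed count, as 9 rose and 1 fell (9 and 1 adjusted over the list alone): Krt8 and its partner Krt18 (2.75 ± 0.33) rose most, while Epcam, an adhesion gene of epithelia and embryonic stem cells, fell by 2.00 ± 0.26. Across the epithelial list the median was 0.44, with 0.54 and 0.25 within the first and second array set. Epithelial genes had camera adjusted p = 0.000735, 0.000815 with the array sets as a block, and adjusted p = 0.157 with an estimated correlation. Growth factors and their receptors (26 measured) included a ligand and its receptor, Kitl (2.09 ± 0.12) and Kit (1.87 ± 0.17), and 14 rose and 1 fell (17 and 1 adjusted over the list alone). The lower one was Vegfd, a lymphangiogenic factor (-0.44 ± 0.14, adjusted p = 0.0254). Leaving out Control replicate 4, 5 or 6 or RA48 replicate 1, 2 or 3 ended its call, with adjusted p from 0.0516 to 0.0702. For this list the median change was 0.45 (0.54 in the first and 0.42 in the second array set). Growth factors and receptors had camera adjusted p = 3.24e-06, 4.6e-05 with the array sets as a block, and adjusted p = 0.065 with an estimated correlation. The imprinted and IGF axis list had Igf2, a fetal growth factor (3.62 ± 0.44), and Igfbp3, an IGF binding protein gene (2.33 ± 0.27), at its head, 8 rose and 0 fell (10 and 0 adjusted over the list alone) of 16, and the median was 0.63, with 0.78 and 0.52 within the first and second array set. Imprinted and IGF axis genes had camera adjusted p = 0.00154, 3.54e-05 with the array sets as a block, and adjusted p = 0.283 with an estimated correlation.

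Of 13 cell cycle inhibitors 6 rose and 0 fell (6 and 0 adjusted over the list alone) at 48 h, with Gas1, a growth arrest gene (3.13 ± 0.20), and Cdkn1a, which encodes the inhibitor p21 (1.35 ± 0.16), rising most. For them changes had a median of 0.56 (0.72 within the first and 0.61 within the second array set). Cell cycle inhibitors had camera adjusted p = 0.000308, 0.000949 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. DNA replication genes went down by less, as 0 rose and 14 fell (1 and 15 adjusted over the list alone) of 32, for example Orc2 of the origin recognition complex (-0.78 ± 0.12) and Ccne1, a cyclin gene (-0.77 ± 0.13). For DNA replication the median change was -0.27 (-0.20 in the first and -0.26 in the second array set). DNA replication genes had camera adjusted p = 0.0466, 0.0462 with the array sets as a block, and adjusted p = 0.391 with an estimated correlation. Within the first and second set alone its adjusted p was 0.077 and 0.0648. That call was lost without Control replicate 1 (adjusted p = 0.0704) or 3 (0.0621) and without RA48 replicate 4 (0.0727) or 5 (0.0821). Proteasome genes shifted lower as well, 1 rose and 11 fell (1 and 13 adjusted over the list alone) of 28. Psmc1 (-0.74 ± 0.14) and Psmc6 (-0.58 ± 0.08), which encode regulatory ATPases of the proteasome, fell most, and Psmd8, a further subunit gene, rose by 0.47 ± 0.11 (0.34 with adjusted p = 0.0665 within the second set). For the proteasome the median was -0.37, with -0.35 and -0.22 within the first and second array set. Proteasome genes had camera adjusted p = 0.00769, 0.00639 with the array sets as a block, and adjusted p = 0.482 with an estimated correlation (0.0655 within the second set alone).

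In all, limma called 4642 of 17863 rows for RA48 versus Control (2124 higher, 2518 lower; 6257 at an unadjusted p under 0.05), including 2985 genes, 1564 of them higher. Of the called rows, 918 changed at least 2-fold, 592 of them upward. In 3241 rows (18.1%) the groups did not overlap, where chance gives 0.433%. The count was 7029 with the array set as a block (3028 higher, 4001 lower), and 6780 (3170, 3610) and 6244 (2568, 3676) within the first and second set. Of the called rows 4624 had 1 direction in both sets, and 3141 were called within each set alone. Agreement in direction is favoured there, as the rows were called on the arrays of both sets. Over all rows, called or not, the changes within the 2 sets correlated by 0.63. Array weights gave 8135 (3421 higher, 4714 lower). The random block gave 1437, with most of them higher (828, against 609 lower), and there Klf4, Vegfd, Psmd8 and Psmc1 lost their calls. Control cells were harvested near confluence whereas retinoic acid was given at lower density, so density is not separated from the treatment.

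RA96 versus RA48 asked what changed over the next 48 h in retinoic acid, from which time in culture is not separated (n = 6 and 5 arrays). Acta2 rose by a further 2.21 ± 0.22, a 4.62-fold change, and Myl9, a myosin light chain of smooth muscle, by 2.04 ± 0.23. Large rises were those of Inhba, which encodes a subunit of activin (3.33 ± 0.28), Adamts5, an aggrecan-cleaving protease gene (3.01 ± 0.20), Postn, which encodes the matrix protein periostin (2.99 ± 0.47), and Pdgfc, a platelet-derived growth factor gene (2.40 ± 0.14). The largest rise was that of Serpinb6b, a serine protease inhibitor gene (3.76 ± 0.30), and Prss23, a serine protease gene (2.54 ± 0.17), Sytl2, a vesicle transport gene (2.74 ± 0.20), and Emp1, a membrane protein gene (2.65 ± 0.33), rose too. Lefty1, which had risen at 48 h, fell by 3.65 ± 0.19, and Trh, the thyrotropin-releasing hormone gene, by 3.13 ± 0.31. Sox2 changed by -2.23 ± 0.51, by -2.75 within the first set and by -1.99 (adjusted p = 0.137) within the second. Prex2, an activator of Rac (-2.19 ± 0.34), Prtg, a surface protein gene of the early embryo (-2.11 ± 0.23), Car2, a carbonic anhydrase gene (-2.11 ± 0.34), Large2, a glycosyltransferase gene (-2.08 ± 0.21), and Irx3, a homeodomain factor (-2.06 ± 0.20), fell as well. The arrays of the groups did not overlap for any of these genes, and the highest adjusted p was 0.00426 (Sox2). Cnn1 (0.51 ± 0.20, adjusted p = 0.0782), Nanog (-0.44 ± 0.17, 0.0757), Rarb (-0.21 ± 0.20, 0.512) and Myh11 (0.30 ± 0.60, 0.772) did not pass. With the array set as a block Cnn1 (0.55, adjusted p = 0.0436) and Nanog (-0.31, 0.0125) passed. Under the random block neither Cnn1 (0.64, adjusted p = 0.329) nor Nanog (-0.33, 0.735) did. Within the first and second set Cnn1 changed by 0.76 (0.000168) and 0.57 (0.00687), and Nanog by -0.50 (0.0106) and -0.12 (0.338). Rarb changed there by -0.02 (0.932) and 0.03 (0.921), and Myh11 by -0.11 (0.516) and -0.27 (0.464). For Cnn1, Rarb and Myh11 the change fitted without the set lay outside both of these values, so it carries part of the difference between the sets. Nanog also passed without Control replicate 3 (adjusted p = 0.0477) and without RA48 replicate 4 (0.0386) or 5 (0.0187).

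Of 18 contractile genes of smooth muscle 8 rose and 0 fell (9 and 0 adjusted over the list alone) between 48 and 96 h, and the median change was 0.59 (0.58 in the first and 0.55 in the second array set). Smooth muscle contractile genes had camera adjusted p = 8.22e-07, 2.52e-07 with the array sets as a block, and adjusted p = 0.227 with an estimated correlation. Integrin and focal adhesion genes had 27 measured members, of which 13 rose and 2 fell (15 and 2 adjusted over the list alone). Cav1, the caveolin gene (2.15 ± 0.25), and Fhl1, a LIM-domain gene (1.80 ± 0.12), rose most, and the integrin genes Itgb5 (-0.62 ± 0.16) and Itga2 (-0.52 ± 0.14, and -0.15 with adjusted p = 0.429 within the second set) fell. For this list the median was 0.31, with 0.40 and 0.35 within the first and second array set. Integrins and focal adhesion genes had camera adjusted p = 6.8e-08, 1.47e-08 with the array sets as a block, and adjusted p = 0.0823 with an estimated correlation. Matrix proteases and their inhibitors (18 measured) shifted higher, as 10 rose and 2 fell (12 and 2 adjusted over the list alone), with Adamts5 and Adamts1, a related protease gene (1.46 ± 0.16), in front. Mmp9, a gelatinase gene, fell by 0.74 ± 0.18 (1 of its 2 probes was called, and the change was -0.44 with adjusted p = 0.0736 within the first set). Serpinf1, which encodes an antiangiogenic serpin, differed by -0.90 ± 0.30 (adjusted p = 0.0375), a call that ended without RA48 replicate 3, 4 or 5 or RA96 replicate 1, 2 or 3, with adjusted p from 0.0557 to 0.087. For the protease list changes had a median of 0.68 (0.69 within the first and 0.61 within the second array set). Matrix proteases and inhibitors had camera adjusted p = 6.8e-08, 1.22e-07 with the array sets as a block, and adjusted p = 0.0638 with an estimated correlation. Interstitial matrix genes (27 measured) included Postn and Col8a1, a collagen gene (2.08 ± 0.23), and 12 rose and 1 fell (13 and 1 adjusted over the list alone). The lower one, Fbln1, a fibulin gene (-0.60 ± 0.18), lost its call without RA96 replicate 1 (adjusted p = 0.0507). For the interstitial matrix the median change was 0.59 (0.48 in the first and 0.42 in the second array set). Interstitial matrix genes had camera adjusted p = 1.62e-05, 7.86e-05 with the array sets as a block, and adjusted p = 0.429 with an estimated correlation. Among 31 TGF-beta and BMP signalling genes 10 rose and 3 fell (10 and 3 adjusted over the list alone), with Inhba and Tgfb2, a ligand gene (2.37 ± 0.16), rising most. Those that fell were receptor genes: Acvr2b (-0.98 ± 0.16), Tgfbr3 (-0.47 ± 0.14; 1 of 2 probes called, -0.11 with adjusted p = 0.442 within the second set, and adjusted p = 0.0689, 0.0657 and 0.0798 without RA48 replicate 1, 2 and 3) and, named after its values were seen, Tgfbr1 (-0.29 ± 0.08). For TGF-beta and BMP signalling the median was 0.16, with 0.21 and 0.15 within the first and second array set. TGF-beta and BMP signalling genes had camera adjusted p = 0.000183, 0.000316 with the array sets as a block, and adjusted p = 0.0647 with an estimated correlation.

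Of 32 DNA replication genes 0 rose and 15 fell (0 and 19 adjusted over the list alone) between 48 and 96 h, with Cdt1, which licenses origins (-0.93 ± 0.19), and Mcm5, a helicase subunit gene (-0.72 ± 0.11), and changes had a median of -0.37 (-0.40 within the first and -0.22 within the second array set). DNA replication genes had camera adjusted p = 8.88e-06, 4.24e-05 with the array sets as a block, and adjusted p = 0.0816 with an estimated correlation. In mitosis 0 rose and 9 fell (0 and 10 adjusted over the list alone) of 26, with Cdc25b, a phosphatase that starts mitosis (-1.0 ± 0.17, and -0.93 with adjusted p = 0.0845 within the second set), and Ccnb2, a cyclin gene (-0.73 ± 0.11). For mitosis the median change was -0.33 (-0.40 in the first and -0.34 in the second array set). Mitosis genes had camera adjusted p = 2.17e-05, 1.78e-06 with the array sets as a block, and adjusted p = 0.137 with an estimated correlation. Among 20 pluripotency genes 1 rose and 7 fell (1 and 9 adjusted over the list alone): Lefty1 and Sox2 fell most and Klf4 rose by 0.93 ± 0.21 (0.64 with adjusted p = 0.139 within the second set). For pluripotency the median was -0.27, with -0.33 and -0.18 within the first and second array set. Pluripotency genes had camera adjusted p = 0.000628, 0.0042 with the array sets as a block, and adjusted p = 0.303 with an estimated correlation. The retinoic acid response list (15 measured) was not called, as 1 rose and 2 fell (1 and 2 adjusted over the list alone). Nr2f2, a nuclear receptor gene, rose by 0.68 ± 0.15 (0.35 with adjusted p = 0.135 within the first set). Stra6, a retinol transporter gene (-1.38 ± 0.17), and Pbx2, a homeodomain cofactor (-0.61 ± 0.12), fell. For that list changes had a median of -0.03 (-0.17 within the first and 0.03 within the second array set). Retinoic acid response genes had camera adjusted p = 0.496, 0.354 with the array sets as a block, and adjusted p = 0.849 with an estimated correlation.

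For RA96 versus RA48 limma called 3540 rows (1857 higher, 1683 lower; 5932 at an unadjusted p under 0.05), including 1949 genes, 938 of them higher. Of the called rows, 606 changed at least 2-fold, 462 of them upward. In 1839 rows (10.3%) the groups did not overlap, where chance gives 0.433%. The count was 5726 with the array set as a block, 6697 within the first set and 2267 within the second. Most called rows were then lower with the block (2725 higher, 3001 lower) and within the first set (3114, 3583), and higher within the second (1164, 1103). Of the called rows 3491 had 1 direction in both sets, and 994 were called within each set alone. Over all rows, called or not, the changes within the 2 sets correlated by 0.44. Leaving out 1 array moved the count of 3540 by more than 1.5 times: without RA48 replicate 1, 2 or 3 it was 2239, 2305 or 2227. Array weights gave 10273 (4938 higher, 5335 lower) and the random block 248 (159, 89). The weights favoured first-set arrays in RA48 and second-set arrays in RA96, so the count of 10273 mixes in the difference between the sets. Without RA48 replicate 4 most called rows were lower (2016, 2098). With the random block the calls of Sox2, Prex2, Itgb5, Itga2, Serpinf1, Mmp9, Fbln1, Acvr2b, Tgfbr3, Cdt1, Mcm5, Cdc25b, Ccnb2, Klf4, Nr2f2 and Pbx2 ended (Sox2 with adjusted p = 0.47).

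Puromycin versus RA96 asked what followed when cells after 96 h of retinoic acid were exposed to puromycin for 48 h (n = 6 and 6 arrays), a step meant to remove cells that do not use the Acta2 promoter. Acta2 itself differed by 0.52 ± 0.21 and did not pass (adjusted p = 0.163), although all 6 Puromycin arrays (lowest 2.13) lay above all 6 RA96 arrays (highest 2.03). With the array set as a block it did (0.59, adjusted p = 0.0302), as within the second set (0.77, 0.00208), and within the first it was 0.25 (0.518). Among the largest rises were those of the chemokine genes Ccl2 (2.01 ± 0.24) and Cxcl12 (1.46 ± 0.19), Vcam1, a vascular adhesion gene (1.59 ± 0.22), Lox, a collagen cross-linking enzyme gene (1.99 ± 0.21), and Tnfrsf11b, which encodes osteoprotegerin (2.06 ± 0.29, and 2.25 with adjusted p = 0.0516 within the first set). Clca3a1, a chloride channel accessory gene, rose most (2.64 ± 0.17), and Tm4sf1, a membrane protein gene (1.90 ± 0.25), and S100a6, a calcium-binding protein gene (1.42 ± 0.16), rose too. Rarb fell by 1.56 ± 0.19, Hoxa5 by 1.58 ± 0.18 and Col18a1 by 1.68 ± 0.09. The largest fall was that of Ppbp, a platelet chemokine gene (-2.87 ± 0.34), and Serpinf1 (-1.65 ± 0.29), Wfdc2, a secreted protease inhibitor-like gene (-1.46 ± 0.22), Car2 (-1.38 ± 0.32) and Gas1 (-1.38 ± 0.19) fell as well. The arrays of the groups did not overlap for any of these rises and falls, and the highest adjusted p was 0.0112 (Car2). Cnn1 (-0.32 ± 0.19, adjusted p = 0.446), Nanog (0.00 ± 0.16, 0.995) and Myh11 (-0.18 ± 0.57, 0.928) did not pass. Within the first set Cnn1 was called lower (-0.58, adjusted p = 0.00477), and within the second it differed by -0.28 (0.0962).

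Neither smooth muscle list was called in this step. Among 18 contractile genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), the riser being Cald1, which encodes caldesmon (0.59 ± 0.12; 2 of its 3 probes were called, and it was 0.54 with adjusted p = 0.0787 within the first set). For contractile genes the median change was 0.09 (0.09 in the first and 0.26 in the second array set). Smooth muscle contractile genes had camera adjusted p = 0.903, 0.468 with the array sets as a block, and adjusted p = 0.98 with an estimated correlation, and the mean of -0.05 differed from the median in sign. Among 17 smooth muscle regulators 2 rose and 0 fell (2 and 0 adjusted over the list alone): Klf4 (1.15 ± 0.20) and Zeb2, a zinc-finger repressor (0.40 ± 0.09, and 0.33 with adjusted p = 0.0691 within the first set). For regulators the median was 0.04, with 0.03 and 0.04 within the first and second array set. Smooth muscle regulators had camera adjusted p = 0.529, 0.354 with the array sets as a block, and adjusted p = 0.9 with an estimated correlation. Epithelial genes shifted lower, 0 rose and 5 fell (0 and 7 adjusted over the list alone) of 18: Krt19, a keratin gene (-1.07 ± 0.15), Cdh1, which encodes E-cadherin (-0.94 ± 0.14), and, named after their values were seen, Krt8 (-0.51 ± 0.14), Spint2 (-0.39 ± 0.09) and Cldn6 (-0.38 ± 0.09). For the epithelial list changes had a median of -0.36 (-0.27 within the first and -0.28 within the second array set). Epithelial genes had camera adjusted p = 1.03e-05, 7.39e-07 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. Retinoic acid response genes shifted lower too, 0 rose and 5 fell (1 and 6 adjusted over the list alone) of 15: Rarb, Stra6 (-1.31 ± 0.17) and, named after their values were seen, Meis2 (-0.59 ± 0.15), Nr2f2 (-0.56 ± 0.15) and Pbx2 (-0.54 ± 0.11). For this list the median change was -0.35 (-0.49 in the first and -0.23 in the second array set). Retinoic acid response genes had camera adjusted p = 4.01e-05, 0.000248 with the array sets as a block, and adjusted p = 0.0816 with an estimated correlation. Of 14 Hox genes 0 rose and 2 fell (0 and 3 adjusted over the list alone), Hoxa5 and Hoxb5 (-0.65 ± 0.11), and the median was -0.10, with -0.00 and -0.16 within the first and second array set. Hox genes had camera adjusted p = 0.00991, 0.0122 with the array sets as a block, and adjusted p = 0.0823 with an estimated correlation.

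Actin cytoskeleton genes shifted higher after puromycin, 4 rose and 0 fell (4 and 0 adjusted over the list alone) of 20: Gsn, which encodes gelsolin (1.29 ± 0.22), Arpc1b of the actin-branching complex (0.92 ± 0.10), and, named after their values were seen, Msn (0.55 ± 0.12) and Wdr1 (0.43 ± 0.09). For them changes had a median of 0.20 (0.15 within the first and 0.35 within the second array set). Actin cytoskeleton genes had camera adjusted p = 0.00642, 4.85e-05 with the array sets as a block, and adjusted p = 0.649 with an estimated correlation (0.0769 within the first set alone). In the interstitial matrix 3 rose and 0 fell (3 and 0 adjusted over the list alone) of 27: Lox, Col8a1 (1.10 ± 0.22, and 0.59 with adjusted p = 0.0523 within the first set) and, named after its values were seen, Thbs1 (1.06 ± 0.16). For the interstitial matrix the median change was 0.14 (0.14 in the first and 0.51 in the second array set). Interstitial matrix genes had camera adjusted p = 0.0234, 0.000248 with the array sets as a block, and adjusted p = 0.807 with an estimated correlation (0.226 within the first set alone). That call was lost without RA96 replicate 1 (adjusted p = 0.0822) or 3 (0.126) and without Puromycin replicate 4 (0.107), 5 (0.156) or 6 (0.145). The list of the unfolded protein and amino acid response, which inhibited translation could touch, was not called. Of 19 members 0 rose and 2 fell (1 and 2 adjusted over the list alone), Atf3, a stress factor (-0.55 ± 0.13), and Shmt2, an enzyme gene of serine metabolism (-0.64 ± 0.19, adjusted p = 0.047, and -0.40 with 0.0711 within the second set). The call of Shmt2 ended in 15 of 23 fits with 1 array left out, all but those without Control replicate 2 or 3, RA48 replicate 4, RA96 replicate 1 or 3, or Puromycin replicate 4, 5 or 6, with adjusted p from 0.0501 to 0.134. For this list the median was -0.03, with -0.07 and 0.08 within the first and second array set. Unfolded protein and amino acid response genes had camera adjusted p = 0.634, 0.96 with the array sets as a block, and adjusted p = 0.924 with an estimated correlation. The p53 targets were not called either, as 2 rose and 1 fell (3 and 1 adjusted over the list alone) of 16: Cdkn1a (0.96 ± 0.15) and Fas, a death receptor gene (0.65 ± 0.15, and 0.25 with adjusted p = 0.343 within the first set), rose, and Sesn1, a sestrin gene (-0.64 ± 0.13, and -0.75 with adjusted p = 0.0656 within the second set), fell. For p53 targets changes had a median of 0.07 (-0.11 within the first and 0.09 within the second array set). Targets of p53 had camera adjusted p = 0.375, 0.474 with the array sets as a block, and adjusted p = 0.789 with an estimated correlation.

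For Puromycin versus RA96 limma called 942 rows (567 higher, 375 lower; 3091 at an unadjusted p under 0.05), including 679 genes, 408 of them higher. Of the called rows, 84 changed at least 2-fold, 48 of them upward. In 822 rows (4.6%) the groups did not overlap, where chance gives 0.216%. The count was 2281 with the array set as a block (1302 higher, 979 lower), and 1691 (879, 812) and 1638 (940, 698) within the first and second set. Of the called rows 940 had 1 direction in both sets, and 388 were called within each set alone. Over all rows, called or not, the changes within the 2 sets correlated by 0.40. Array weights gave 2609 (1444 higher, 1165 lower) and the random block 17 (8, 9), and of the genes named here Ccl2, Clca3a1, Col18a1, Hoxa5 and Rarb kept their calls in the latter. Puromycin cells were also 48 h older, so puromycin and time in culture are not separated.

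**Figure D2:**
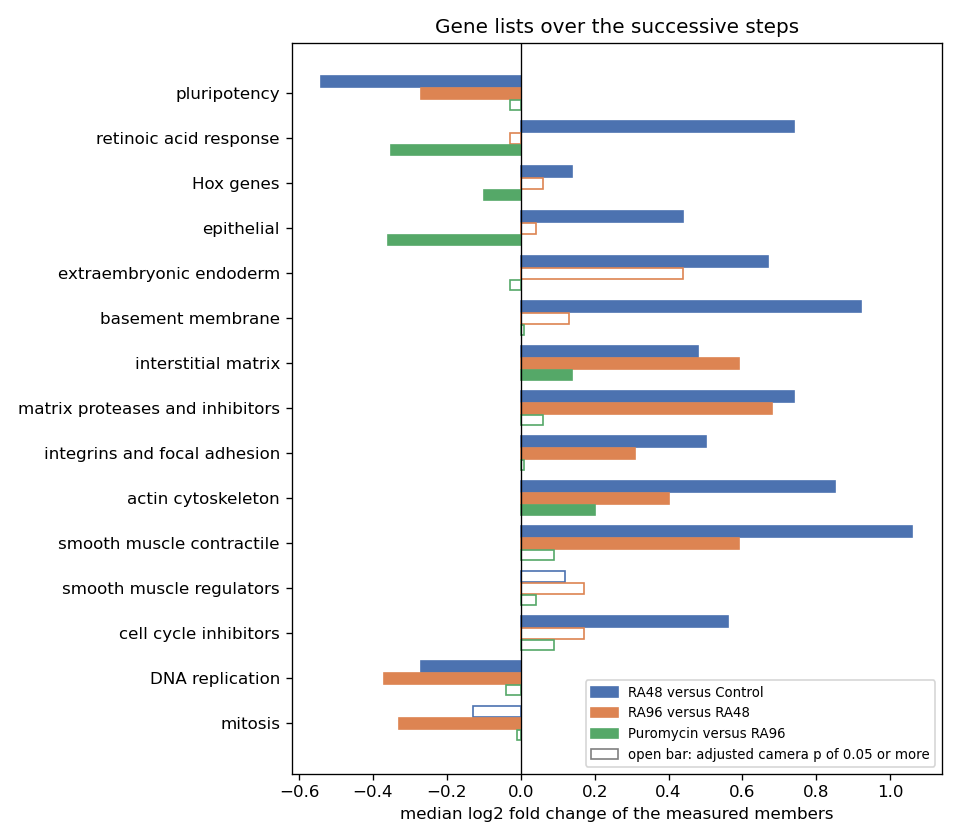
Median log2 change (x axis) of 15 gene lists (y axis) in the 3 successive steps, RA48 versus Control, RA96 versus RA48 and Puromycin versus RA96, with open bars where camera gave no call. The smooth muscle contractile list has medians of 1.06, 0.59 and 0.09, and the retinoic acid response list 0.74, -0.03 and -0.35.

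RA96 versus Control gave the change over 96 h of retinoic acid, without puromycin (n = 6 and 6 arrays). Retinoic acid, time in culture and cell density are not separated in it. Acta2 rose by 6.77 ± 0.21, a 109-fold change, by 7.35 within the first and 6.21 within the second array set. Anxa1 (6.25 ± 0.17), Pmp22 (5.79 ± 0.19) and Prss23 (5.75 ± 0.16) rose next. Trh (-5.13 ± 0.30), Pim2 (-4.58 ± 0.13), Dnmt3b (-4.50 ± 0.14) and Sox2 (-4.46 ± 0.49) fell most. Rarb (2.81 ± 0.19) and Cnn1 (1.48 ± 0.19) rose, Nanog fell by 1.15 ± 0.16, and Myh11 (0.37 ± 0.57, adjusted p = 0.627) did not pass. For the genes that passed the groups did not overlap, and the highest adjusted p was 5.8e-06 (Nanog). Of 18 contractile genes 16 rose and 0 fell (16 and 0 adjusted over the list alone), led by Acta2 and Myl9 (4.37 ± 0.22), and the median change was 1.77 (1.75 in the first and 1.60 in the second array set). Smooth muscle contractile genes had camera adjusted p = 1.64e-10, 9.16e-15 with the array sets as a block, and adjusted p = 0.153 with an estimated correlation. Of 20 pluripotency genes 2 rose and 13 fell (2 and 13 adjusted over the list alone), with Klf4 (1.72 ± 0.20) and Klf2 (1.04 ± 0.19) as the risers, and the median was -1.34, with -1.33 and -1.17 within the first and second array set. Pluripotency genes had camera adjusted p = 3.06e-11, 7.87e-11 with the array sets as a block, and adjusted p = 0.0816 with an estimated correlation. Of 18 matrix proteases and inhibitors 15 rose and 0 fell (15 and 0 adjusted over the list alone), with Adamts5 (3.93 ± 0.19) and Adamts1 (2.84 ± 0.15), and changes had a median of 1.35 (1.26 within the first and 1.12 within the second array set). Matrix proteases and inhibitors had camera adjusted p = 1.99e-08, 4.78e-10 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. Of 17 basement membrane genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with Nid1 (4.22 ± 0.17) and Col4a5, a collagen gene (2.80 ± 0.28), and the median change was 1.24 (1.28 in the first and 1.25 in the second array set). Basement membrane genes had camera adjusted p = 2.26e-08, 8.11e-08 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. Of 13 cell cycle inhibitors 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Gas1 (3.76 ± 0.19) and Cdkn2b, an inhibitor of cyclin D kinases (2.31 ± 0.19), rising most, and Rbl1, a relative of the retinoblastoma protein, falling by 0.38 ± 0.08, and the median was 0.89, with 0.64 and 0.91 within the first and second array set. Cell cycle inhibitors had camera adjusted p = 0.0001, 0.000316 with the array sets as a block, and adjusted p = 0.027 with an estimated correlation. In all, 8239 rows were called (3585 higher, 4654 lower; 9396 at an unadjusted p under 0.05), including 4472 genes, 2073 of them higher, and 1784 rows changed at least 2-fold, 1204 of them upward. In 4649 rows (26.0%) the groups did not overlap, where chance gives 0.216%. The count was 10487 with the array set as a block, and 9348 and 9183 within the first and second set, with 8187 called rows of 1 direction in both and 5874 called within each. Over all rows the changes within the 2 sets correlated by 0.80. The random block gave 2783 (1458 higher, 1325 lower), where Rbl1 lost its call.

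Puromycin versus Control set the last point of the protocol against the undifferentiated cells (n = 6 and 6 arrays). Acta2 rose by 7.30 ± 0.21, a 157-fold change, by 7.61 and 6.98 within the first and second array set. Anxa1 (6.96 ± 0.17), Prss23 (6.72 ± 0.16), Serpinb6b (6.08 ± 0.29), S100a6 (5.99 ± 0.16), Emp1 (5.31 ± 0.32), Pmp22 (5.19 ± 0.19) and Thbs1, a thrombospondin gene (5.17 ± 0.16), made up the largest rises with it. The largest falls were those of Sox2 (-5.70 ± 0.49), Trh (-5.53 ± 0.30), Dnmt3b (-5.04 ± 0.14), Pim2 (-4.70 ± 0.13), Utf1 (-3.82 ± 0.12), Gpr37 (-3.60 ± 0.12), Magel2 (-3.58 ± 0.13) and Prex2 (-3.54 ± 0.33). The Control mean of Prex2 holds 1 array at 5.89, replicate 5, with the others from 3.27 to 3.64. Rarb (1.25 ± 0.19) and Cnn1 (1.17 ± 0.19) rose, Nanog fell by 1.15 ± 0.16, and Myh11 (0.19 ± 0.57, adjusted p = 0.813) did not pass. For the genes that passed the groups did not overlap, and the highest adjusted p was 3.28e-05 (Cnn1).

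Of 18 contractile genes 16 rose and 0 fell (16 and 0 adjusted over the list alone), with Acta2 and Myl9 (4.56 ± 0.22) in front, and the median change was 1.57 (1.73 in the first and 1.38 in the second array set). Smooth muscle contractile genes had camera adjusted p = 1.39e-09, 6.03e-14 with the array sets as a block, and adjusted p = 0.184 with an estimated correlation. Of 17 smooth muscle regulators 9 rose and 1 fell (9 and 1 adjusted over the list alone): Klf4 (2.87 ± 0.20) and Gata6 (2.44 ± 0.17) rose most and Sp1, a general transcription factor, fell by 0.71 ± 0.10. For regulators the median was 0.41, with 0.41 and 0.42 within the first and second array set. Smooth muscle regulators had camera adjusted p = 0.00995, 0.0137 with the array sets as a block, and adjusted p = 0.291 with an estimated correlation. Of 20 actin cytoskeleton genes 14 rose and 0 fell (14 and 0 adjusted over the list alone), with Tmsb4x (3.43 ± 0.37) and Gsn (2.87 ± 0.22), and changes had a median of 1.65 (1.5 within the first and 1.71 within the second array set). Actin cytoskeleton genes had camera adjusted p = 3.06e-11, 2.53e-17 with the array sets as a block, and adjusted p = 0.193 with an estimated correlation. Of 27 interstitial matrix genes 15 rose and 0 fell (15 and 0 adjusted over the list alone), with Thbs1 and Ccn2, a connective tissue growth factor (5.03 ± 0.17), and the median change was 1.29 (1.07 in the first and 1.48 in the second array set). Interstitial matrix genes had camera adjusted p = 2.1e-07, 4.78e-10 with the array sets as a block, and adjusted p = 0.409 with an estimated correlation. Of 20 pluripotency genes 2 rose and 12 fell (2 and 12 adjusted over the list alone), the risers being Klf4 and Klf2 (2.06 ± 0.19), and the median was -1.36, with -1.37 and -1.29 within the first and second array set. Pluripotency genes had camera adjusted p = 2.6e-10, 2.24e-10 with the array sets as a block, and adjusted p = 0.0823 with an estimated correlation. Of 25 chromatin regulators 1 rose and 16 fell (1 and 16 adjusted over the list alone). Smarcd1, a remodelling complex subunit gene (-1.37 ± 0.07), and Dnmt3a, a DNA methyltransferase gene (-1.37 ± 0.11; 2 of its 3 probes were called and the other changed by 0.01), fell most, and Hmga2, a chromatin protein of embryonic cells, rose by 2.26 ± 0.27. For chromatin regulators changes had a median of -0.62 (-0.65 within the first and -0.45 within the second array set). Chromatin regulators had camera adjusted p = 0.0056, 0.00187 with the array sets as a block, and adjusted p = 0.482 with an estimated correlation.

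DNA replication genes were lower at the end of the protocol than in Control, 1 rose and 25 fell (1 and 25 adjusted over the list alone) of 32. The helicase genes Mcm7 (-1.09 ± 0.19) and Mcm5 (-1.06 ± 0.10) fell most, and Rrm2, a ribonucleotide reductase gene, rose by 0.58 ± 0.08. For DNA replication the median change was -0.68 (-0.62 in the first and -0.67 in the second array set). DNA replication genes had camera adjusted p = 0.0001, 0.000123 with the array sets as a block, and adjusted p = 0.0823 with an estimated correlation. Of 26 mitosis genes 1 rose and 18 fell (1 and 18 adjusted over the list alone): Bub1b, a checkpoint kinase gene (-1.22 ± 0.11), and Cenpa, a centromere histone gene (-1.01 ± 0.16), fell most and Prc1, a spindle midzone gene, rose by 0.65 ± 0.10. For mitosis the median was -0.47, with -0.50 and -0.49 within the first and second array set. Mitosis genes had camera adjusted p = 0.00187, 0.000949 with the array sets as a block, and adjusted p = 0.216 with an estimated correlation. Of 16 p53 targets 10 rose and 3 fell (10 and 3 adjusted over the list alone): Cdkn1a (3.16 ± 0.15) and Fas (2.92 ± 0.15) rose most, and Sesn1 (-1.03 ± 0.13), Pmaip1, a pro-death gene (-0.76 ± 0.15), and, named after its values were seen, Aen (-0.24 ± 0.08) fell. For p53 targets changes had a median of 0.69 (0.72 within the first and 0.59 within the second array set). Targets of p53 had camera adjusted p = 0.000517, 0.00164 with the array sets as a block, and adjusted p = 0.159 with an estimated correlation. In all, 8263 rows were called (3545 higher, 4718 lower; 9393 at an unadjusted p under 0.05), including 4619 genes, 2140 of them higher, and 1870 rows changed at least 2-fold, 1210 of them upward. In 5054 rows (28.3%) the groups did not overlap, where chance gives 0.216%. The count was 10763 with the array set as a block, and 10782 and 8505 within the first and second set, with 8172 called rows of 1 direction in both and 5657 called within each. Over all rows the changes within the 2 sets correlated by 0.77. The random block gave 3100 (1566 higher, 1534 lower). Over all 38 lists, camera calls held with an estimated correlation for basement membrane and cell cycle inhibitors in RA48 versus Control, epithelial genes in Puromycin versus RA96, and basement membrane, cell cycle inhibitors and matrix proteases and inhibitors in RA96 versus Control. In Puromycin versus Control they held for cell cycle inhibitors (median change 1.0, adjusted p = 0.027 with an estimated correlation) and for matrix proteases and inhibitors (1.59, 0.0352), and in RA96 versus RA48 for 0 lists.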

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

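Of the tests below, those of a shared shift, of the reference pool, of retinoic acid no longer given, of cell loss and of a response to puromycin, and the fits with the array sets as a block, were chosen after the results were seen.

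In 25 of 468 pairs of a named gene and a group, in 23 genes, 1 array lay far from the others, where chance gives 23.4. In Control they were Adamts1 replicate 3 (-1.53, others -1.09 to -0.87), Krt8 replicate 3 (-2.44, others -2.03 to -1.86), Thbs1 replicate 3 (-2.47, others -2.09 to -1.91), Vcam1 replicate 3 (-3.76, others -3.09 to -2.83), Pmaip1 replicate 3 (0.77, others 0.13 to 0.32), Hmga2 replicate 2 (1.69, others 1.98 to 2.14), Ccl2 replicate 5 (-1.32, others -0.53 to -0.20), Prex2 replicate 5 (5.89, others 3.27 to 3.64), Prss23 replicate 5 (-1.80, others -2.38 to -2.17) and Sox2 replicate 5 (8.18, others 4.12 to 5.22). In RA48 they were Fas replicate 4 (0.87, others 0.43 to 0.55), Orc2 replicate 4 (0.79, others 1.15 to 1.25), Pmaip1 replicate 4 (-0.44, others -0.29 to -0.23), Rbl1 replicate 4 (0.38, others 0.74 to 0.81), Gpr37 replicate 5 (-0.25, others 0.05 to 0.07), Sytl2 replicate 5 (-1.76, others -0.73 to -0.35) and Tshz1 replicate 5 (2.10, others 1.68 to 1.74). In RA96 they were Acvr2b replicate 2 (-0.36, others 0.07 to 0.24), Cdt1 replicate 2 (-0.16, others 0.33 to 0.62), Gas1 replicate 2 (1.46, others 1.75 to 1.86) and Gata6 replicate 4 (1.85, others 2.39 to 2.61). In Puromycin they were Adamts5 replicate 4 (1.97, others 1.71 to 1.80), Gpr37 replicate 4 (0.09, others -0.51 to -0.30), Cdc25b replicate 6 (-0.54, others -1.77 to -1.5) and Itga2 replicate 1 (-1.54, others at most -1.20). Among the 1166 rows left out as probable control spots 256 differed between the groups in the limma F test. In RA96 versus Control 281 of them were called, with log2 changes of up to 3.94 in size. In Puromycin versus Control 209 were called, with changes of up to 5.26. Whether they are all control spots is thus uncertain.

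The arrays of every group fell into 2 sets. Cultures of 1 set being further along the same course is argued against by a correlation over rows of -0.09 between shift and Control to Puromycin change. Compression of the ratios by 1 factor as the main source is argued against by the 5.5% of the shift's variance that the mean ratio explains. A smaller compression stays open. In Puromycin the ratios had an SD of 1.033 to 1.068 in the first set and 0.863 to 0.874 in the second. In RA48 the SD was 0.94 to 0.963 in the first set and 0.807 and 0.96 in the second. A shift on the side of the reference or the hybridization stays open, as the shifts of any pair of groups correlated over rows by 0.52 to 0.80. A reference RNA pool of another make-up stays open: 5 marker genes of liver, blood and muscle not looked at before had a median shift of -0.85 (one-sided permutation p = 0.002 over 10000 random lists), but lists matched for the mean ratio had a median of -0.71 (one-sided permutation p = 0.322), so strongly negative rows in general were lower in the first set. A narrower low end of the ratios in the second set and a difference between cultures grown at separate times stay open too.

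The retinoic acid response list was lower in Puromycin than in RA96, and the labels do not say whether retinoic acid was still given. Whether its withdrawal contributes stays open: the median change of 4 Hox genes that rose at 48 h minus that of 1551 other genes that rose then was -0.41, but the falls of Hoxa5 and Hoxb5 were known when this test was chosen, so it decides nothing. Loss of cells that do not use the Acta2 promoter cannot be told apart from withdrawal, as the contractile list changed by 0.09. A response to puromycin of the protein synthesis machinery cannot be told apart either. It was judged only by the unfolded protein and amino acid response list, of which 0 of 19 members were called higher by limma. That list holds no ribosomal protein or tRNA synthetase genes, so it is an indirect gauge. Time in culture is confounded with this step.

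The extraembryonic endoderm list was higher in RA48 than in Control. Its 10 members on no other list had a median change of 0.49, 6 of them called higher, close to the 0.5 that had been set for endoderm cells, so that explanation stays open. Its 9 members shared with other lists had a median of 0.92, a difference of 0.44 (two-sided exact permutation p = 0.142), so a signal from shared matrix and smooth muscle genes stays open as well.

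Over 100 splits of the arrays into groups of the same sizes, 1 split, the real one, gave as many called rows as 9406 among the 4 groups (highest other 3779), 4642 in RA48 versus Control (3762), 3540 in RA96 versus RA48 (3065), 8239 in RA96 versus Control (5166) and 8263 in Puromycin versus Control (4080). In Puromycin versus RA96 3 splits gave 942 or more (highest other 5191). That highest split followed the array sets, as did the highest in RA96 versus RA48: in each, the percentages of first-set arrays in its groups lay 83.3 apart. Calling several times the real count, the split in Puromycin versus RA96 points to the structure of the arrays. With the array set as a block 1 split gave as many for each: 12718 among the groups (highest other 1), 7029 in RA48 versus Control (5675), 5726 in RA96 versus RA48 (2718), 2281 in Puromycin versus RA96 (150), 10487 in RA96 versus Control (6654) and 10763 in Puromycin versus Control (6326). Counts as high as the real ones were thus rare, at most 3 of the 100 splits with the real one included. These splits treat the arrays as varying independently. In the random block fit, however, arrays of 1 group and set had a consensus correlation of 0.68. That value includes the set shift that the groups share. The sets were also defined around the real groups. Chance differences between cultures thus cannot be excluded by these splits.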

How the results depend on the processing

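The array set as a block, each set alone, the random block and ratios read as log2 were chosen after seeing the data. Settings fixed beforehand that moved a count of called rows by more than 1.5 times were array weights (8135 for RA48 versus Control, 10273 for RA96 versus RA48 and 2609 for Puromycin versus RA96), an adjusted p under 0.01 (1596 for RA96 versus RA48 and 437 for Puromycin versus RA96), the replicate number as a block (1784 for Puromycin versus RA96) and a 2-fold change (918, 606, 84, 1784 and 1870 for RA48 versus Control, RA96 versus RA48, Puromycin versus RA96, RA96 versus Control and Puromycin versus Control), which by construction asks for more. Deviations from the group means correlated by more than 0.1 in 30 of 33 pairs of arrays with 1 replicate number (-0.46 to 0.67). The exceptions, the pairs with RA96 replicate 2, lie across the array sets, and 4 of 23 arrays best matched an array of their own number, so the arrays were not treated as pairs. Array weights stopped before their tolerance was met. In RA48 they were 3.59 to 3.93 in the first set and 0.28 and 0.33 in the second. In RA96 they were 0.47 and 0.66 in the first set and 1.01 to 1.85 in the second. Weighted changes in RA96 versus RA48 thus mix in the difference between the sets. With the array set as a block the counts were 7029, 5726 and 2281 for the first 3 comparisons, within the first set 6697 and within the second 2267 for RA96 versus RA48, and 1691 and 1638 for Puromycin versus RA96. The random block gave 2851 for any difference and 1437, 248, 17, 2783 and 3100 for the comparisons, and a 2-fold change with ratios read as log2 gave 16, 7, 0, 68 and 85. Leaving out 1 array gave 8895 to 9741 for any difference and 4168 to 4692, 2227 to 4198, 641 to 1083, 7583 to 8420 and 7640 to 8396, with 2239, 2305 and 2227 for RA96 versus RA48 without RA48 replicate 1, 2 and 3. Rules on missing values changed nothing, since none are missing. Of 185 gene results the random block ended 47 calls and the array set as a block 0. Only the groups compared ended 4 calls (Serpinf1 and Fbln1 in RA96 versus RA48, Shmt2 and Fas in Puromycin versus RA96), quantile normalization 2 (Klf4 in RA48 versus Control, Shmt2), median-centred arrays 1 (Shmt2) and array weights 1 (Serpinf1), and 1 probe each of Gata6 in RA48 versus Control, Mmp9 and Tgfbr3 in RA96 versus RA48 and Cald1 in Puromycin versus RA96 was not called. Of 45 list results an estimated correlation ended 34 calls. The 11 results that it left the same include lists that camera had not called. For 2 lists that camera called fry made no call, but fry tests whether the members move 1 way and does not compare them with other genes, so it answers another question. Acta2 in Puromycin versus RA96 was also called with quantile normalization (0.54) and with only the groups compared (0.52). Cnn1 in RA96 versus RA48 was called with quantile normalization (0.52), and Nanog in RA96 versus RA48 with the replicate number as a block (-0.40). Array weights called Rarb in RA96 versus RA48 (-0.64), Nanog in RA96 versus RA48 (-0.74) and Myh11 in RA96 versus RA48 (1.28), and Myh11 in RA48 versus Control was called within the first set (0.31). Elsewhere Myh11 was not called, and it changed sign in RA48 versus Control with quantile normalization (-0.04), array weights (-1.0) and 1 array left out (-0.24 to 0.31), in RA96 versus RA48 with the set as a block (-0.20), the random block (-0.11) and within the first (-0.11) and second (-0.27) set, in Puromycin versus RA96 likewise (0.14, 0.07, 0.07 and 0.16) and with 1 array left out (-0.45 to 0.03), in RA96 versus Control within the second set (-0.05), and in Puromycin versus Control with array weights (-0.35) and 1 array left out (-0.03 to 0.41). Rarb reversed in RA96 versus RA48 within the second set (0.03), and 1 probe of Dnmt3a in Puromycin versus Control (0.01). Lists that were not called changed sign too: retinoic acid response in RA96 versus RA48 within the second set (0.03) and with 1 array left out (-0.15 to 0.02), and in Puromycin versus RA96 smooth muscle regulators with 1 array left out (-0.03 to 0.04), p53 targets within the first set (-0.11), and the unfolded protein and amino acid response with the set as a block (0.03, and 0.03 with an estimated correlation), within the second set (0.08) and with 1 array left out (-0.15 to 0.03). In RA96 versus RA48 and Puromycin versus RA96 the sign of Myh11 within both sets opposed its sign without the set. There the uneven spread of the groups over the sets gave the sign. Except where stated, the cause of the other changes was not tested.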

Other observations

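In Puromycin versus Control (n = 6 and 6 arrays) camera called 1 list of another cell type, extraembryonic endoderm. It shares 9 members with other lists, such as basement membrane, and these were not tested apart in this comparison. Of its 19 genes 12 rose and 2 fell (12 and 2 adjusted over the list alone), the latter, named after their values were seen, being Lrp2 (-0.71 ± 0.27) and Cited1 (-0.40 ± 0.14). The median change of the endoderm list was 0.80 (0.55 and 0.85 within the first and second array set), with camera adjusted p = 0.000258, 0.000656 with the sets as a block and adjusted p = 0.0823 with an estimated correlation. The epithelial (median 0.20, camera adjusted p = 0.324), mesoderm (-0.01, 0.741, with a mean of 0.14) and neural crest (0.67, 0.216) lists were not called, nor were those that follow. Of 18 neural genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), among them, named after their values were seen, Dpysl3 (3.60 ± 0.32), Gap43 (2.15 ± 0.20), Tubb2b (1.03 ± 0.25), Nes (0.69 ± 0.24), Crmp1 (0.64 ± 0.12), Stmn2 (-0.43 ± 0.08), Neurog1 (-0.38 ± 0.13) and Nefl (-0.33 ± 0.12). The median change of the neural list was 0.11 (0.09 and 0.15 within the first and second array set), with camera adjusted p = 0.498, 0.23 with the sets as a block and adjusted p = 0.849 with an estimated correlation. Of 19 cardiac muscle genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), named after their values were seen: Nppb (2.26 ± 0.32), Myl2 (1.82 ± 0.48), Myl7 (1.31 ± 0.14), Nppa (0.67 ± 0.08), Myh7 (-0.63 ± 0.11), Hand1 (-0.43 ± 0.15) and Mybpc3 (-0.41 ± 0.12). Their median was 0.12 (0.23 and 0.12 within the sets), with camera adjusted p = 0.529, 0.299 with the sets as a block and adjusted p = 0.849 with an estimated correlation. Of 10 endothelial genes 4 rose and 4 fell (4 and 4 adjusted over the list alone), named after their values were seen: Flt1 (1.34 ± 0.10), Kdr (0.89 ± 0.10), Pecam1 (0.78 ± 0.17), Cdh5 (0.70 ± 0.17), Nos3 (-0.66 ± 0.12), Eng (-0.61 ± 0.21), Sox18 (-0.53 ± 0.19) and Esam (-0.31 ± 0.10). Their median was 0.23 (0.30 and 0.19), with camera adjusted p = 0.478, 0.573 with the sets as a block and adjusted p = 0.853 with an estimated correlation. Of 8 skeletal muscle genes Myf6, named after its values were seen, was called (0.78 ± 0.29), and none when adjusted over the list alone. That list had a median of 0.20 (0.07 and 0.26), with camera adjusted p = 0.881, 0.68 with the sets as a block and adjusted p = 0.93 with an estimated correlation. Of 9 blood and macrophage genes limma called 0 (0 adjusted over the list alone), with a median of 0.08 (-0.07 and 0.13), camera adjusted p = 0.908, 0.729 with the sets as a block and adjusted p = 0.948 with an estimated correlation.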
